A study of Mus musculus with 2 samples.

How the data were processed

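RNA of 2 mouse osteosarcoma cell lines was compared on Affymetrix mouse genome arrays, with 1 array for the parental Dunn line and 1 for its highly metastatic derivative LM8. Per the labels' protocols, both lines were grown with 10% fetal bovine serum and 1% non-essential amino acids, and 10 µg of RNA went into each array. The deposited values were linear probe set intensities computed by the authors with MAS5, per the submitters' processing notes. The version and settings of MAS5 were not given in the sources used here. In the values themselves, each array of 45101 probe sets had a 2% trimmed mean of 100, no log and no floor. The experiment sheets of the arrays named the same chip type and scanner and the same hybridisation and scan day for both.

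The 64 control probe sets were kept out of gene counts and scaling. The remaining 45037 probe sets were put on a common 2% trimmed mean, which multiplied the signals by 1.00 on both arrays. The floor of each array was its median over these probe sets, 21.06 for Dunn and 18.96 for LM8. A signal under the floor was set to it, and a probe set was measured if at least 1 array lay above its floor, which held for 25144 probe sets. Detection calls were not used here. Among 154 probe sets of genes silent in most tissues, such as olfactory receptors, 9.74% lay above the floor in Dunn and 4.55% in LM8.

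Gene names came from the platform's annotation table, updated through gene identifiers against a table of the GRCm38.p6 mouse assembly. Of 35890 probe sets in that table, 34958 had 1 gene symbol and 932 had several, and 9160 further non-control probe sets were unnamed. Gene identifiers matched for 99.4% of the probe sets with 1 symbol. A gene took the value of its measured probe set with the highest mean log2 signal, which gave 11830 measured genes out of 18193. Differences are log2 of LM8 over Dunn, and a fold with an array at its floor is a lower bound for that probe set, written as at least N-fold; other probe sets of the gene can give less. Folds hold for these 2 arrays only.

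With 1 array per line no test of significance was possible and no p-value is given. Genes were counted by a fixed rule, at least 2-fold apart. The SD of the log2 ratio between probe sets of a gene was the only spread at hand for a single gene. It reflects technical and isoform differences and not replicate error. For each of 33 gene lists the median log2 ratio of the measured members was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The list's place among these is a description of the 2 arrays. A list is called outside the random range if its median lay beyond the central 95%.

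The lists, the counting rule, the floor and the alternatives were fixed before the data were examined. So was the rule for named genes: the 10 largest differences in each direction among genes with at least 2 measured probe sets, all 2-fold apart in the same direction, up to 4 members of each list with the largest log2 ratios, and 18 genes named in advance. Other list members are named only to spell out a short count, and were chosen after their values were seen. The alternatives were 4 other scalings (array medians, quantile normalization, signal-dependent centring with a lowess span of 0.3, bacterial hybridisation controls), 3 other floors, a pseudocount at the array median (this and the setting with no floor also dropped the filter on dim probe sets), 2 other gene summaries, a 3-fold rule, a rule that all probe sets of a gene be 2-fold apart, and lists without members at the floor. Chromosome medians used gene order in GRCm38.p6, for 11809 measured genes, with windows of 50 neighbouring genes.

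The steps were tested on simulated LM8 and Dunn arrays with noise of SD 0.305 (log2) on 11090 genes. All 100 genes set 4-fold apart and all 100 set 8-fold apart were recovered, and 6 of 10890 unchanged genes were called. The changed genes were drawn only from those with a mean signal more than 8 times the higher floor. The noise was the median SD between probe sets of a gene, under the pooled SD of 0.464. The run shows that the steps work on bright genes and gives no error rate for the real arrays. Of 200 random lists, 12 fell outside the random range. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.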

Results

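Transcript levels were measured in 2 mouse osteosarcoma cell lines that differ in their ability to spread. Dunn is a parental osteosarcoma line that seldom forms metastases, and LM8 is a line derived from it that metastasises to the lung at a high rate. Each line was hybridised to 1 array, so no difference below has a replicate check and the number of arrays limits the precision. Both arrays carried 45101 probe sets, and signals over the 45037 non-control probe sets ran with a Spearman correlation of 0.870 across probe sets, which are not independent replicates. The 3' to 5' signal ratio was 0.708 for Gapdh in Dunn and 0.789 in LM8, and 1.26 and 1.16 for beta-actin.

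The comparison asked which transcripts differ between the poorly and the highly metastatic line. Among 11830 measured genes, 770 were at least 2-fold higher in LM8 and 1046 at least 2-fold lower, and 140 and 169 of them were at least 4-fold apart. Genes of the cell cycle, sterol synthesis, the interferon response, the extracellular matrix and glycolysis were higher in LM8 as groups. Antigen presentation genes and macrophage markers were lower. The brightest probe set of the collagen gene Col9a1 was at least 31.6-fold higher, with a signal of 665 in LM8, and its other probe set had a log2 ratio of 2.34 (46.6 against 235). Thbs2, which encodes a matrix thrombospondin, was at least 27.2-fold higher on its brightest probe set, and a dimmer one above both floors had a log2 ratio of 2.53.

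Car3, a carbonic anhydrase gene, was 16.0-fold higher in LM8, and Fosl1, a subunit of the AP-1 transcription factor, was 11.3-fold higher. Col8a1 was at least 10.4-fold higher, the surface glycoprotein gene Cd24a at least 8.06-fold, and Kcnn4, a calcium-activated potassium channel gene, at least 7.75-fold. Mis18a, needed to load the centromeric histone, was 6.12-fold higher. Gch1, which starts tetrahydrobiopterin synthesis, and the cyclin gene Ccna2 were each 5.99-fold higher. In the other direction, the complement gene C2 had a signal of 573 in Dunn and was at least 30.2-fold lower in LM8. Ppp1r3c, a glycogen-targeting phosphatase subunit, was at least 29.5-fold lower on its brightest probe set, with signals of 161 and 20.2 on the other, and the iron exporter gene Slc40a1 was at least 28.8-fold lower. Cyp1b1, a cytochrome P450 gene, was at least 18.6-fold lower, the fucosidase gene Fuca2 15.2-fold and the adaptor gene Sorbs2 13.98-fold. The dimmer measured probe sets of Fuca2 and Sorbs2, with LM8 at its floor, had log2 ratios of -1.10 and -1.01. St6gal1, a sialyltransferase gene, was 9.70-fold lower, Prune2 8.44-fold, the growth factor gene Pdgfc 8.06-fold and Endou at least 7.63-fold. The rule that picked these 20 genes required at least 2 measured probe sets, all 2-fold apart in the same direction.

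The higher genes made up 42.4% of those called, but 56.9% (1025 against 775) with arrays centred on their medians and 65.9% (1237 against 639) with scaling on the hybridisation controls, whose mean log2 ratio was -0.24 (SD 0.10, 12 probe sets). The median of all genes, -0.08, became 0.07 and 0.16 in these scalings, and with neither the floor nor the filter on dim probe sets the counts were 2553 and 3351 among 18193 genes. Of the called genes, 159 of the higher and 262 of the lower had an array at its floor on the brightest probe set. The SD of the log2 ratio between probe sets of a gene had a median of 0.30 over 5521 genes. For 810 called genes with further measured probe sets, the next brightest went the same way in 718, was 2-fold apart that way in only 371 (45.8%) and 2-fold apart the opposite way in 6. Of 65 named genes 2-fold apart with 2 or more measured probe sets, 27 had another probe set under 2-fold or opposite, and for 8 of these (Ezr, Ptn, Csf1r, Uty, Itgav, Slc7a11, Dnajc3 and Peg3) it lay under 0.2 in log2 ratio in the gene's direction.

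**Figure D1:**
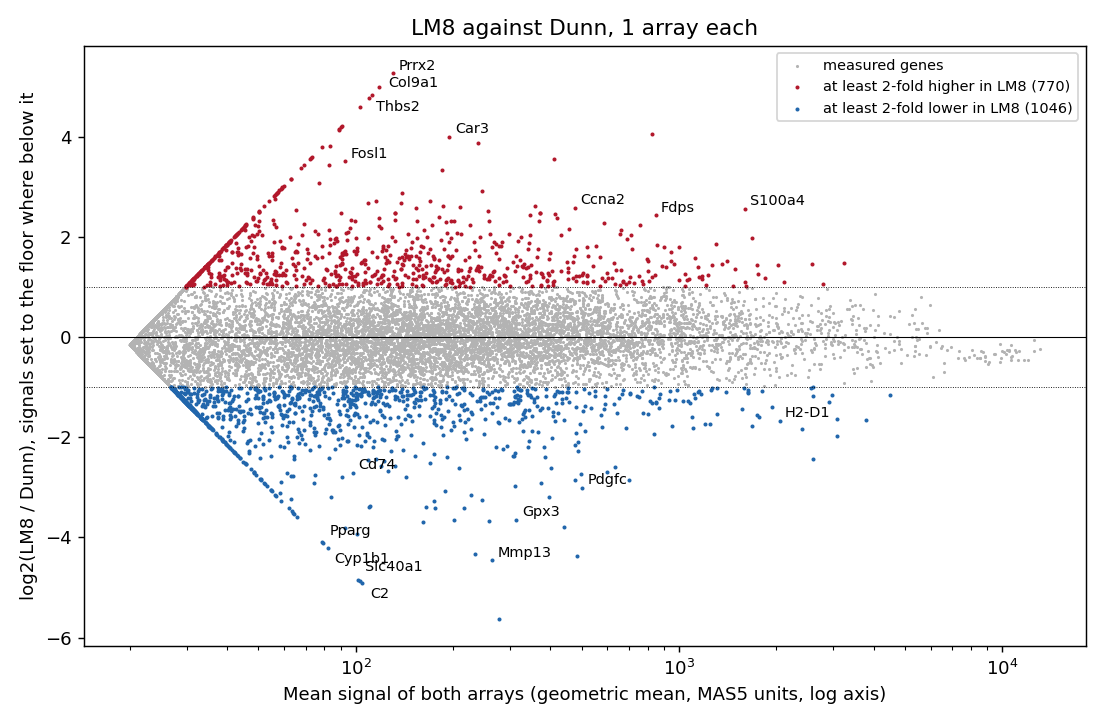
Log2 ratio of LM8 to Dunn (vertical axis) against the geometric mean signal of both arrays in MAS5 units (horizontal log axis), with 1 point per measured gene. Red points are the 770 genes at least 2-fold higher in LM8 and blue points the 1046 at least 2-fold lower; the slanted edges are genes with 1 array at its floor.

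**Figure D2:**
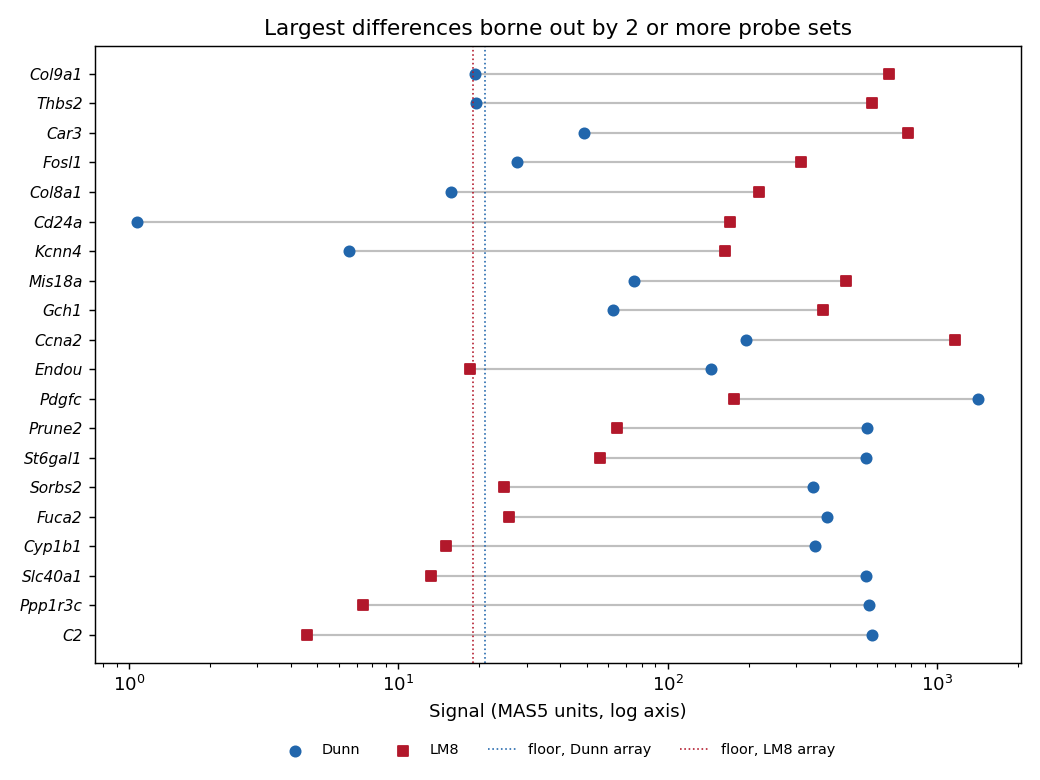
Signals in MAS5 units (log axis) of the brightest probe set of the 20 genes with the largest differences among those with at least 2 agreeing probe sets, as blue circles for Dunn and red squares for LM8, 1 array each. Dotted lines are the floors of the arrays, 21.06 and 18.96; C2 in Dunn lies at 573 and Col9a1 in LM8 at 665.

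Cell cycle and DNA replication genes stood highest of the 33 lists. Of 37 measured members, 25 were at least 2-fold higher in LM8, none was 2-fold lower and 12 lay between, with a median log2 ratio of 1.498 that exceeded all 10000 random lists. Each line was grown as 1 culture, so growth state and cell line were not separated. Besides Ccna2, the spindle checkpoint kinase gene Bub1 was 5.71-fold higher, the kinetochore motor gene Cenpe 5.59-fold and Cdc20, an activator of the anaphase-promoting complex, 4.70-fold. Among 20 measured p53 targets and tumour suppressors, 8 were 2-fold lower in LM8, 1 was higher and 11 lay between. Gadd45a, a DNA damage response gene, was 9.55-fold lower, Trp53inp1 5.03-fold, Zmat3 2.72-fold and the antiproliferative gene Btg2 2.36-fold. The higher member was Cdkn2c, an inhibitor of cyclin-dependent kinases. Their median of -0.28 lay inside the random range (percentile 6.07), and below it with the floor at the 75th percentile (-0.65) or with probe sets averaged (-0.40). Cdkn2a was below the floor in both lines, and Trp53 was not analysed here. Of 25 apoptosis and death receptor genes, 2 were higher, 2 lower and 21 between, with a median of -0.12 (percentile 36.8). Casp1 was 4.06-fold and Birc3 at least 2.13-fold higher in LM8, whereas the pro-apoptotic gene Bid was 3.32-fold lower. The death receptor gene Fas had a signal of 41.9 in Dunn, near the floor, and was at least 2.21-fold lower.

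Extracellular matrix genes were higher in LM8 as a group, with members going both ways. Of 35 measured, 16 were at least 2-fold higher, 4 lower and 15 between, and the median of 0.50 exceeded all 10000 random lists. After Thbs2 and Col8a1, Tgfbi was 4.997-fold higher and Fbln5, which takes part in elastic fibre assembly, 4.91-fold. The lower members were Fn1, Loxl1, Dcn and Lama4, with log2 ratios of -1.83 for the fibronectin gene Fn1 and -1.41 for the decorin gene Dcn. Matrix proteases and their inhibitors were split, with 7 of 27 higher, 5 lower and 15 between, and a median of 0.05 (percentile 73.1). The collagenase gene Mmp13 was 21.97-fold lower in LM8, from 1240 to 56.5, and Mmp11 was 4.12-fold lower, as were Adamts5, Fap and Ctsd by at least 2-fold. Timp4, an inhibitor of metalloproteinases, was at least 5.66-fold higher, the osteoclast-associated protease gene Ctsk 4.51-fold and Timp1 2.18-fold. Mmp2 had signals of 80.5 and 125, and Mmp9 and Plau were below the floor in both lines.

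Bone and cartilage genes showed no common direction. Of 16 measured osteoblast lineage genes, 2 were higher (Omd and Smpd3), 3 lower (Ank, Ibsp and Pth1r) and 11 between, with a median of -0.27 (percentile 5.66). The osteomodulin gene Omd was 5.01-fold higher in LM8, Smpd3 2.35-fold higher, the pyrophosphate transporter gene Ank 2.58-fold lower and the bone sialoprotein gene Ibsp 2.48-fold lower. Alkaline phosphatase (Alpl) stood at 1266 in Dunn and 1739 in LM8, and Col1a1 at 2399 and 3537. Runx2 and Spp1 were not analysed here. Of 8 chondrocyte genes, Col9a1 alone was 2-fold higher, 3 were lower (Hapln1 by at least 5.32-fold, Sox6 by 2.45-fold and Col11a1 by at least 2.24-fold) and 4 lay between, with a median of -0.49 (percentile 7.70).

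Genes of the actin cytoskeleton and migration were higher in LM8 by a small median of 0.29, above 9948 of 10000 random lists. Of 33 measured, 6 were 2-fold higher and 25 between, and the brightest probe sets of Cnn2 and Ezr were 2-fold lower. Smooth muscle actin (Acta2) was 6.01-fold higher, S100a4, a calcium-binding protein gene linked to metastasis, 5.90-fold with a signal of 3888 in LM8, and the actin-bundling gene Fscn1 3.47-fold. The 2 probe sets of the membrane-cytoskeleton linker gene Ezr opposed each other, with log2 ratios of -2.11 for the brighter and 1.95 for the dimmer, so Ezr has no settled direction. Of 11 regulators of the epithelial-mesenchymal transition, Prrx2, Snai1 and Twist1 were higher, none was 2-fold lower and 8 lay between. Prrx2, a homeobox gene of mesenchyme, was at least 38.5-fold higher on its 1 probe set, with a signal of 810 in LM8. Snai1 was 2.32-fold, Twist1 2.31-fold and Tcf4 1.67-fold higher, and the median of 0.37 lay just inside the random range (percentile 96.6). It lay above the range with probe sets averaged (0.44) and with the floor from silent genes (0.34), and so did the median of 12 genes with the filter on dim probe sets dropped and either no floor (0.51) or a pseudocount (0.42). Integrin and adhesion genes had a median of -0.07 (percentile 52.6), with 1 of 25 higher, 4 lower and 20 between. Itgav was 3.38-fold higher, although its probe sets ranged from -0.09 to 1.76 in log2 ratio. The lower members were Itga8 (at least 4.99-fold), Ncam1 (3.96-fold), Itga5 (2.34-fold) and Sdc2. Cd44 had signals of 859 and 1108, and Itga6 was below the floor in both lines.

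Interferon-stimulated genes were higher in LM8 while antigen presentation genes were lower. Of 31 interferon-stimulated genes, 11 were at least 2-fold higher, 1 (Bst2) lower and 19 between, with a median of 0.75 above all 10000 random lists. Rtp4 was 4.21-fold, the deconjugating protease gene Usp18 3.06-fold, the GTPase gene Irgm1 2.55-fold and the viral RNA sensor gene Ddx58 2.49-fold higher. The median was 0.40 with the floor at the 75th percentile and 0.48 over 36 genes with a pseudocount and no filter on dim probe sets, outside the random range in both. None of 19 antigen presentation genes was 2-fold higher, 7 were lower and 12 lay between, with a median of -0.49 that only 16 of 10000 random lists undercut. Cd74, the invariant chain gene, was 6.54-fold lower, the class I gene H2-D1 3.20-fold (3659 against 1144), the class I transactivator gene Nlrc5 3.01-fold and Tapbpl at least 2.68-fold. Of the 19, 9 lie on chromosome 17, whose measured genes had a median of -0.24 as a whole. Of 15 cytokine and chemokine genes, 1 was higher, 3 lower and 11 between, with a median of -0.52 (percentile 3.25). With the filter on dim probe sets dropped, 33 such genes had a median below the random range, both with no floor (-0.71) and with a pseudocount (-0.35). The chemokine receptor gene Ackr3 was at least 4.04-fold higher, whereas Cxcl16 was at least 2.78-fold, Ptgs2 at least 2.47-fold and Cx3cl1 2.41-fold lower. Cxcr4 was below the floor in both lines.

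As a list, markers of macrophages and osteoclasts were lower in LM8 alongside the antigen presentation genes, mostly at dim signals. Of 21 listed, 10 were measured, 3 were 2-fold lower (Lyz1 by at least 4.65-fold, Csf1r by 2.80-fold and Lyz2 by at least 2.36-fold), none was higher and 7 lay between. Their median of -0.92 undercut all but 4 of 10000 random lists, but that of all 21 lay inside the range with a pseudocount and no filter on dim probe sets (-0.31), and the floor at the 75th percentile left 1 measured marker. Lyz2 had a signal of 44.8 in Dunn, and the probe sets of Csf1r ranged from -1.49 to 0.48 in log2 ratio. The other measured probe set of Lyz1 had a log2 ratio of -0.32. The osteoclast-associated gene Ctsk, listed with the proteases, went the other way and was 4.51-fold higher in LM8. Other cell types gave few measured markers. Of 3 lymphoid genes all lay between (Pax5, Ighm and Cd8a; median -0.12, percentile 55.2). Among 5 endothelial genes Vwf was 2.26-fold lower and 4 lay between (median -0.09, percentile 59.4). The club cell gene Scgb1a1 was at least 2.71-fold lower, and the other 5 of 6 epithelial and lung genes lay between (median -0.35, percentile 39.9). Of 8 muscle and adipocyte genes, Tnnt1 was at least 3.08-fold higher, 2 were lower and 5 lay between (median -0.11, percentile 66.1). The lower ones were Pparg, the regulator of adipocyte formation, by at least 17.2-fold with a Dunn signal of 326, and Cd36 by at least 2.23-fold.

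Sterol synthesis genes were higher in LM8, with 9 of 19 at least 2-fold higher, none lower, 10 between and a median of 0.99 above all 10000 random lists. Fdps, which makes farnesyl diphosphate, was 5.39-fold higher, Idi1 4.99-fold, the sterol carrier gene Stard4 3.71-fold and the squalene synthase gene Fdft1 3.71-fold. Glycolysis and hypoxia genes had a median of 0.43, above 9996 of 10000 random lists, with 3 of 24 higher, 1 lower and 20 between. The lactate exporter gene Slc16a3 was 14.1-fold higher, Bnip3 3.08-fold and Ero1a 2.78-fold, whereas Ndrg1 was 2.08-fold lower. Slc16a3 had a Dunn signal of 22.1, just above the floor. Glutathione and oxidative stress genes had a median of 0.00 (percentile 58.7), with 1 of 26 higher, 3 lower and 22 between. Gpx3, a secreted glutathione peroxidase gene, was 12.5-fold lower, the glutathione transferase genes Gstt1 and Gsta4 at least 11.4-fold and 8.29-fold lower, and Gclm 3.42-fold higher. Genes of endoplasmic reticulum stress and the amino acid response had a median of -0.02 (percentile 47.1), with 3 of 25 higher, 2 lower and 20 between. The cystine transporter gene Slc7a11 was 3.48-fold higher on its brightest probe set and 0.09 in log2 ratio on the other, Dnajc3 was 2.06-fold and Psph 2.03-fold higher, and Ddit3 was 2.88-fold and Trib3 at least 2-fold lower. Of 36 oxidative phosphorylation genes, Ndufb9 was 2.01-fold lower, none was 2-fold higher and 35 lay between (median -0.08, percentile 25.3). None of 26 ribosomal protein genes was 2-fold higher, Rpl14 and Rpl37 were lower by 2.99-fold and 2.04-fold, and 24 lay between. Their median of -0.39 undercut all but 3 of 10000 random lists, but was -0.05 and inside the range with quantile normalization.

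Signalling genes differed singly more than as lists. Of 22 angiogenesis and lymphangiogenesis genes, 4 were higher, 5 lower and 13 between, with a median of -0.06 (percentile 43.7). Ptn, a heparin-binding growth factor gene, was at least 18.6-fold higher on its brightest probe set, while its probe sets ranged down to -0.89 in log2 ratio. Sema3f, Col18a1 and Adamts1 were also 2-fold higher. Besides Pdgfc, Angptl4 was 12.8-fold lower, the matricellular gene Ccn2 4.81-fold, and Sema3a and Vegfb at least 2-fold. Vegfa had signals of 445 in Dunn and 382 in LM8. Wnt signalling had a median of -0.28 (percentile 8.32), with 4 of 30 higher (Axin2, Nkd2, Dkk3 and Fzd2), 6 lower and 20 between. With the filter on dim probe sets dropped, 37 such genes had a median below the random range, both with no floor (-0.41) and with a pseudocount (-0.31). Ccn5 was at least 9.65-fold, Wnt6 7.41-fold and the receptor gene Fzd5 3.34-fold lower, and the feedback gene Axin2 was 3.26-fold higher. TGF-beta and BMP signalling had a median of -0.01 (percentile 63.1), with 5 of 36 higher (Eng, Tgfb3, Fstl3, Id3 and Id1), 4 lower and 27 between. The activin subunit genes Inhbb and Inhba were 8.72-fold and at least 7.16-fold lower, with Ltbp3 and Grem1 as the other lower members, while Eng was 3.56-fold and Tgfb3 3.27-fold higher. Inhbb had an LM8 signal of 19.8, just above the floor, and its other probe set had a log2 ratio of -0.96.

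Of 22 Notch and Hedgehog genes, 5 were higher, 3 lower and 14 between (median -0.08, percentile 60.0). Lfng was at least 4.60-fold, Hey1 at least 3.15-fold and Gas1 2.44-fold higher, with Gli3 and Jag1, whereas Hes1 was 3.10-fold lower, with Notch3 and Maml1. Growth factor receptors and related genes had a median of -0.31 (percentile 5.14), with Fgfr3 as the 1 higher member of 31, 7 lower and 23 between. Igfbp5 was 4.50-fold, Mertk 4.08-fold, Igf1 at least 3.58-fold and the ephrin receptor gene Epha3 3.43-fold lower. With the floor at the 75th percentile this median was -0.55, below the random range. Of 20 immediate early genes, Fosl1 was higher, Egr1 (6.94-fold) and Fos (2.16-fold) were lower, and 17 lay between, among them Ier2 at -0.87 in log2 ratio. Their median was -0.37 (percentile 4.40), and lay below the random range with quantile normalization (-0.39), signal-dependent centring (-0.39) and the floor at the 75th percentile (-0.36).

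Of 12 imprinted genes, Peg3 was 3.32-fold higher, Sgce 7.50-fold, Plagl1 5.74-fold and Dcn 2.65-fold lower, and 8 lay between (median -0.39, percentile 7.01). Among 24 homeobox position genes, Hoxb9 was 2.58-fold higher and Hoxb13 2.10-fold lower, and 22 lay between (median -0.28, percentile 17.8). Transcripts of the sex chromosomes had a median of 0.84 over 4 genes, above 9981 of 10000 random lists, with 2 higher, none lower and 2 between. The Y-linked genes Eif2s3y (at least 7.38-fold higher) and Uty (at least 2.10-fold) were under the floor in Dunn, and Kdm5d, at least 1.54-fold higher on its brightest probe set, had a log2 ratio of 0.01 on another, above both floors. The brightest probe set of Xist stood at 2309 in Dunn and 1824 in LM8, and its others were lower in LM8 with log2 ratios of -1.30 and -0.99. This median was inside the random range with the floor at the 75th percentile (0.18, 2 members) or with probe sets averaged (0.38), and -0.34 with Xist alone, the only member above the floor on both arrays. Scaling on the hybridisation controls moved the medians of the actin cytoskeleton list to 0.53 and of the glycolysis list to 0.67, both of which include the shift of all genes.

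**Figure D3:**
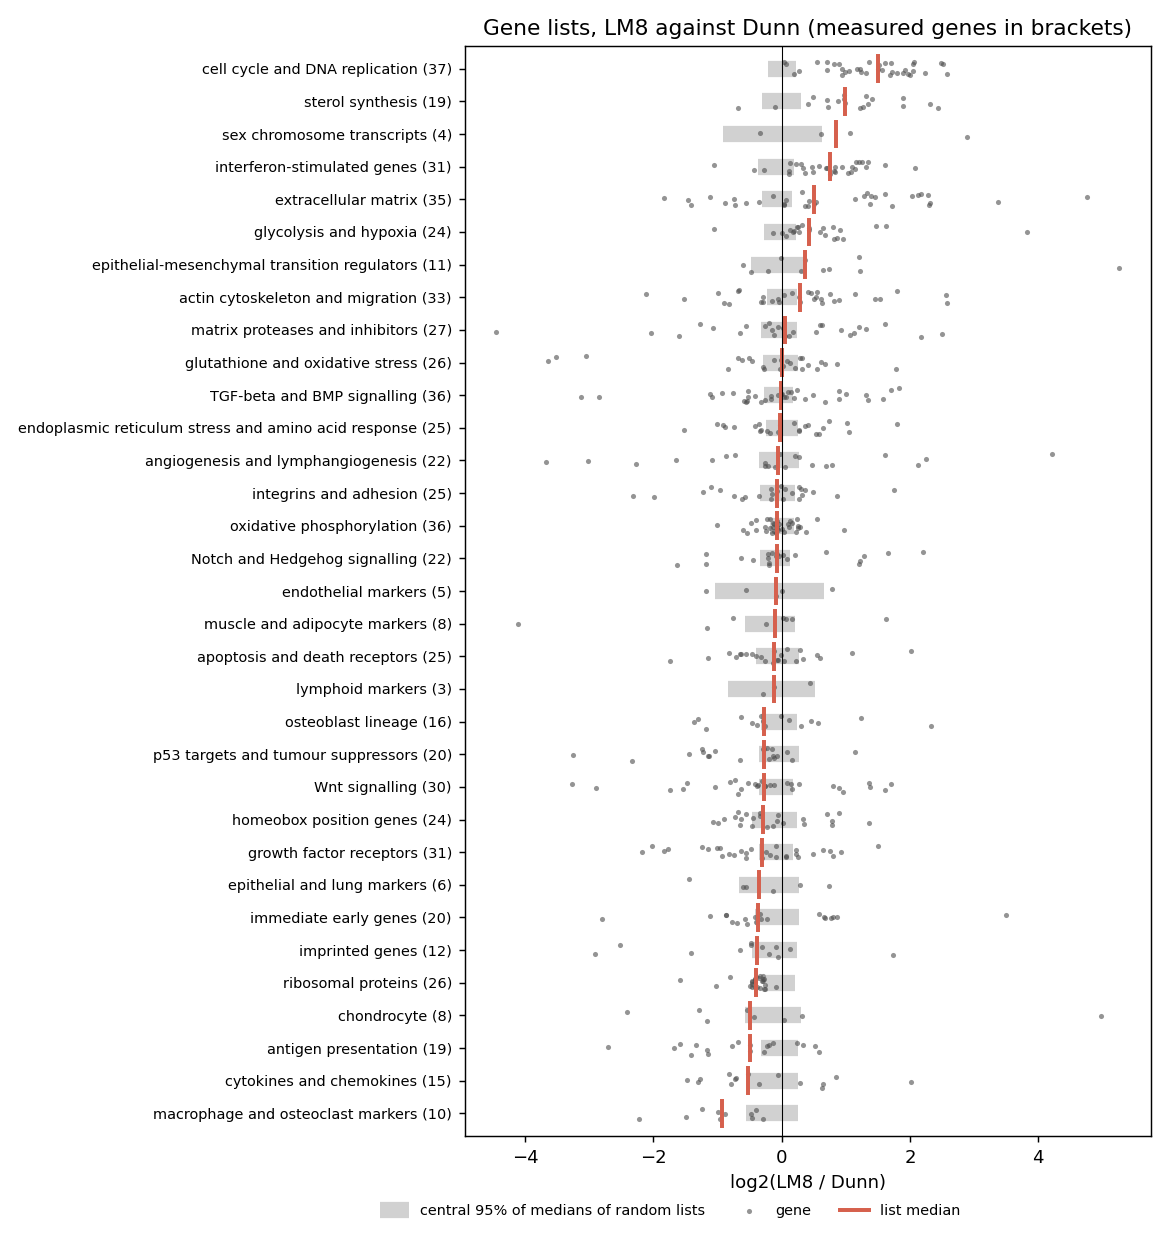
Log2 ratio of LM8 to Dunn (horizontal axis) for the measured members of the 33 gene lists, 1 point per gene, with the list median as a red bar and the central 95% of the medians of 10000 signal-matched random lists as a grey band. The cell cycle median of 1.498 and the sterol synthesis median of 0.99 lie right of their bands, and the macrophage marker median of -0.92 lies left of its band.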

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

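All alternatives below were chosen before the data were examined. Of the lists outside the random range, the cell cycle, sterol, interferon, extracellular matrix, glycolysis, actin and antigen presentation lists stayed outside it in the 8 settings of scaling, floor and gene summary that can alter a list's place; median centring and hybridisation-control scaling move all genes alike and cannot. Cell cycle medians minus that of all genes ran from 1.41 to 1.62. With scaling on the hybridisation controls 1237 genes were higher and 639 lower, and medians were 0.53 (actin), 0.67 (glycolysis), 1.74 (cell cycle), 1.00 (interferon), 1.23 (sterol), -0.15 (ribosomal) and -0.68 (macrophage), since that scaling moves every gene alike. Median centring gave 0.90 (interferon) and -0.24 (ribosomal). The ribosomal median was -0.048 with quantile normalization, inside the random range, and -0.17 with signal-dependent centring, which gave -0.35 for chromosome 15 and turned chromosome 7 from -0.04 to 0.00600; the cause was not tested. A floor at the 75th percentile left 377 higher and 397 lower genes among 7342 measured genes, and an interferon median of 0.40. It both drops dim genes and raises dim signals to the floor, and these effects were not told apart. Dropping both the floor and the filter on dim probe sets gave 2553 and 3351 among 18193 genes, and their parts were not separated. A pseudocount with no filter gave 0.48 (interferon, 36 genes) and -0.31 (macrophage, 21 genes), and averaged probe sets -0.68 (macrophage); the cause was not tested. A 3-fold rule gave 294 and 336 genes, and agreement of all probe sets 113 and 162, by construction. The sex chromosome median reversed to -0.34 without members at the floor, which leaves Xist alone. Of named genes, Cd8a, Egfl7, Vegfa and Kdm5d took the other sign in at least 1 setting, none of them 2-fold apart, and 10 list medians near 0 did so with median centring. Signal over background limits the dim genes, as 421 called genes had an array at its floor on the brightest probe set. Leaving out a replicate was not possible with 1 array per line. No paired analysis was possible because the result comes from no test and each line has 1 array.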

Other observations

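The tests on macrophages, interferon signalling and chromosome 17, and the separate tests of chromosomes 14 and 15, were made after the values were seen. So were the test of cell cycle genes outside all raised chromosomes and the gene choices of the next paragraph. The other tests on the cell cycle list and the test on windows of chromosomes 14 and 15 were set before their own values were seen. Where they name chromosomes, these were chosen after the chromosome medians were seen.

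Slc40a1, the only known iron exporter, was at least 28.8-fold lower in LM8, while the transferrin receptor gene Tfrc was 2.28-fold and the mitochondrial iron importer gene Slc25a37 2.22-fold higher. Tfr2 was 4.75-fold lower, and the ferritin gene Fth1 stood at 10942 in Dunn and 7480 in LM8. As a list, 16 measured iron handling genes had a median of -0.09 (percentile 37.8), with 2 higher, 2 lower and 12 between. Of 10 measured complement genes, 2 were higher, 4 lower and 4 between, with a median of -0.88 (percentile 0.0700). Both lists were drawn up after the values were seen and hold top genes of the same data, Slc40a1 and C2. Their percentiles are therefore no separate support. Besides C2, the C5 gene Hc was at least 7.19-fold, Masp1 3.74-fold and C1s1 2.41-fold lower, whereas the complement inhibitor genes Serping1 and Clu were 6.11-fold and 5.26-fold higher. Among genes with 1 measured probe set, Tmem86a was 49.5-fold lower (1956 against 39.5), the mineralisation inhibitor gene Mgp 20.6-fold and the protease gene Klk4 20.05-fold lower. The phosphoglucomutase-related gene Pgm5 was at least 28.4-fold, the lysosomal protease gene Ctsc at least 24.0-fold, Cthrc1 at least 18.4-fold and Tm4sf1 at least 17.7-fold higher.

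Chromosome medians differed between the lines. By gene order in the GRCm38.p6 assembly, 16 of 20 chromosomes had medians outside the range of random gene sets. Chromosome 14 had a median of 0.34 over 383 genes (71 at least 2-fold higher, 15 lower) and chromosome 15 one of -0.40 over 476 genes (11 higher, 93 lower). Chromosomes 3 (0.22) and 4 (0.18) were higher, and 9 (-0.28), 6 (-0.25), 19 (-0.24) and 17 (-0.24) lower. Of 226 windows of 50 neighbouring genes, 30.1% lay outside the range of random windows.

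For chromosomes 14 and 15 the shift is one of the median, which a few strongly different genes can hardly move. Of the genes of chromosome 14, 73.1% (bootstrap SD 2.31) lay above the median of all genes. On chromosome 15, 72.1% (SD 2.02) lay below it. The SDs in these closing paragraphs come from resampling genes, treated as independent, and give no replicate error. These shares largely restate the shifts for which the chromosomes were picked and are no separate test. Signal-dependent centring moved genes by -0.10 (5th percentile) to 0.10 (95th percentile) about their median change. After it the shifts were 0.418 (SD 0.051) on chromosome 14 and 0.319 (SD 0.033) on chromosome 15 in size. They were smaller among dim genes, 0.309 (SD 0.054) on chromosome 14 and 0.209 (SD 0.067) on chromosome 15. Signal-dependent bias is thus argued against as the whole cause for chromosome 14. The smallest of 3 shifts was first to decide this, and the shift after centring took its place once the values were seen. By the first rule chromosome 15 was left undecided. All 16 of 16 windows lay on their chromosome's side, as a copy number difference would give. These chromosomes were picked for the highest and lowest medians of the same values, which made this outcome likely, so it decides nothing. Each of chromosomes 3, 4, 16, 17 and 19 also had all its windows on the same side of the median of all genes. Of the 16 windows, 3 were inside the range of random windows, among them the last 2 of chromosome 14 (0.11 and 0.02). Yet these last 2 windows held 15 and 8 genes at least 2-fold higher, against 3 lower in each. Whether a copy number difference would span chromosome 14 is thus not settled. Such a difference stays a hypothesis, as no DNA was measured here.

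Array scaling is argued against for the cell cycle genes, since their median exceeded that of all genes by at least 1.49 with quantile normalization and signal-dependent centring, the scalings that move genes unequally. Higher copy number of chromosomes 3, 4 and 14 does not directly reach the 33 members on other chromosomes. These had a median of 1.36, with 22 at least 2-fold higher. Chromosomes 7, 12, 13, 16 and 18 also lay above their random ranges, and the 26 members outside all 8 had a median of 1.43 (SD 0.216), with 16 higher. As 25 of all 37 members were 2-fold higher, neither of these medians could have been under 2-fold, so they are no separate test. Indirect effects of the raised chromosomes on genes elsewhere were not tested. The growth state of the cultures cannot be told apart from the cell line, because there was 1 culture per line. Faster proliferation of LM8 may also account for the pattern, and was not tested.

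The antigen presentation genes were lower although interferon-stimulated genes outside that list had a median of 0.75. This lay above the random range's upper end of 0.19, which argues against less interferon signalling as a general cause. The interferon list does not separate kinds of interferon, so less signalling by 1 kind was not tested. Macrophages in the Dunn culture stay open. The 4 markers above the floor on both arrays had a median -0.43 from that of the antigen presentation genes, with a bootstrap SD of 0.38. Fcer1g, a marker far above both floors, had a signal of 716 in Dunn and 387 in LM8. Lyz2 (44.8 in Dunn), Cd68 (26.2) and Tyrobp (26.3) were too near the floor of 21.06 to exclude macrophages. Lower dosage of chromosome 17, which holds the H2 genes, stays open too. The 10 members elsewhere had a median only -0.17 from that of all genes, which met the reading first set for dosage, but 4 of them were 2-fold lower and Erap1 was higher (log2 ratio 0.59), so this median was then taken to decide nothing. The 9 members on chromosome 17 lay -0.45 from its other genes, inside the random range that ends at -0.50.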
